A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

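The series holds 16 libraries of Saccharomyces cerevisiae. Per the labels, cells were grown in rich medium at 30 °C and fixed with 0.8% formaldehyde for 1 h on ice. Lysates were digested with RNase I, 40S and 80S complexes were separated, and RNA of about 18 to 85 nt was made into libraries, after immunoprecipitation through a FLAG tag for the selected samples. The submitters' processing notes name CASAVA 1.8, Bowtie 1.2.2, Bowtie2 2.2.6, TopHat2 2.1.0 and the genome build R64, with no role or order. Strand-specific counting, treatment of reads that map to several places, and removal of duplicates are not given in the sources used here. Footprints of paralogs and of overlapping or antisense genes are therefore uncertain, and intervals cover counting error only.

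The gene table gives the authors' footprint counts per gene as whole numbers, not normalized, in 5 areas of each transcript for 6 libraries of 40S. How footprints were assigned to the areas is not given in the sources used here. The authors' metagene tables hold counts of 5′ ends from −80 to +30 around start and stop codons by footprint length from 18 to 98 nt, for 3 libraries each of unselected 40S and 80S. The authors' tables of 5′ and 3′ ends around start codons give means over genes as fractions, with the authors' 95% limits. Coverage per nucleotide over GCN4, RPG1, TIF35, PRT1 and SUI3 was deposited as whole-number signal, not scaled to library size. A deposited list of cap sites gives genomic positions for 190 genes and was not used.

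Samples were grouped by the titles in the labels. The tables name a column eIF2α for number 1-3 where the labels name eIF2β. It was taken as the eIF2β-bound library, the only selected 40S library with that number. No count column was left without a sample. Of 5818 gene IDs, 5776 matched a locus tag in the RefSeq table of build R64, 42 did not and were kept under their own names, and 75 genes had no count. Positions are those of that table, 1-based. Nothing states that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. In the factor-bound 40S group, that spread also holds the differences between eIF3a, eIF3c and eIF2β, with 1 library each. It is therefore not the spread between replicates of any of these factors.

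Counts of each area were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr by group, TMM scaling on the counts of that area, and the quasi-likelihood test of the 3 factor-bound against the 3 unselected 40S libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold is therefore relative to the median gene of that area. Each standard error is the absolute log2 fold divided by the square root of the test's F. Gene lists of at least 3 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists, the tests, the named genes and most alternatives were fixed before the data were examined. Of the gene tests, only that of 5′ UTRs was planned for 40S. The start codon and coding-region tests, and those of stop codons and 3′ UTRs, were added after seeing which areas the table holds.

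Genes are named by a fixed rule: among genes past the threshold with every library of 1 group above every library of the other, the 10 largest rises and 10 largest falls, and in every comparison the subunits of eIF3 and eIF2 and GCN4. Members of the lists were named as examples after their values were seen. The list of mitochondrially encoded genes had 0 members in the table and was not tested.

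Area shares carry 95% Wilson intervals. Single values were compared by two-sided exact permutation tests in SciPy 1.17.1 (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, with figures in matplotlib 3.10.9). The smallest p is 0.1 for 3 libraries against 3 and 0.0571 for 3 against 4. The windows at the start codon (−14 to −12) and stop codon (−17 to −14), the length classes (up to 23, 24 to 33, and 34 nt or longer), the 3′ end classes, the 75 nt window and the shares between genes were chosen after seeing the tables. GCN4 peaks are local maxima of the mean unselected 80S coverage, smoothed over 5 nt, with a prominence of at least 0.1 of the highest, and windows reach 15 nt to each side. That rule was also set after a look at the coverage. Without a genome sequence the upstream AUG codons of GCN4 were not placed. The planned GCN4 test of eIF3a-bound 80S was replaced by the groups that the table holds. The point from which coverage rises is the first 50 nt bin after which every bin keeps more than 2 times the median ratio of bins before the midpoint. Its fold is the median bin ratio after that point over the median before it, and the fold from summed coverage was added after seeing the data.

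Library numbers 1-1, 1-2 and 1-3 mark the same tagged strain in both groups, and deviations from group means correlated within each number (0.44, 0.41 and 0.40 for 5′ UTRs, 0.59, 0.49 and 0.43 for start codons, 0.32, 0.26 and 0.26 for coding regions). The numbers therefore pair the samples, and a fit with the number as a block was run beside the unblocked one. Other alternatives were DESeq2 1.42.0 (its size factors, and its Wald test), no count filter, library size from all areas, leaving out each library, other windows and class limits, and other divisions of the coding sequences.

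The gene test was tested on simulated data with 200 changed genes. It recovered 37.0% of 2-fold and 93.0% of 4-fold changes for 5′ UTRs (1947 genes), 34.8% and 98.9% for start codons (3763 genes) and 47.4% and 98.9% for coding regions (4666 genes), with 2 of 116, 6 of 128 and 6 of 146 calls false. Comparisons planned between 40S and 80S or between eIF3a-bound and unselected 80S in gene counts, of coverage at the cap, and of 80S with mRNA were not analysed here.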

Results

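Translation complex profiling sequences the RNase I footprints that formaldehyde-fixed small ribosomal subunits (40S) and whole ribosomes (80S) leave on mRNA, so that scanning and initiating subunits are seen beside elongating ribosomes. In the selective form, complexes that hold a FLAG-tagged initiation factor are pulled down before the footprints are sequenced. The yeast Saccharomyces cerevisiae carried the tag on eIF3a (gene TIF32, listed as RPG1 in the reference), on eIF3c (NIP1) or on eIF2β (SUI3), named eIF2α in the count and coverage tables. eIF3 is the scaffold of the pre-initiation complex and eIF2 carries the initiator tRNA. The 16 libraries comprised 3 of unselected 40S, 1 each of 40S bound by eIF3a, eIF3c and eIF2β, 5 of unselected 80S, 3 of eIF3a-bound 80S, 1 of eIF3c-bound 80S and 1 of mRNA.

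The gene table held counts for 6 libraries of 40S footprints over 5818 genes, each divided into 5′ UTR, start codon, coding region, stop codon and 3′ UTR. Unselected 40S libraries 1-1, 1-2 and 1-3 held 2800652, 1595793 and 1891531 counts. The eIF3a-bound, eIF3c-bound and eIF2β-bound 40S libraries held 3403297, 4440991 and 4486412. Gene counts of 80S and mRNA libraries were not analysed here. The 80S libraries entered through metagene counts around start and stop codons, coverage over GCN4, and coverage over 4 initiation factor genes.

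The comparison of factor-bound with unselected 40S asks where on mRNA subunits carry these factors. Footprints in 5′ UTRs made up 9.52% ± 0.404 (SD, n = 3) of the unselected 40S libraries and 20.9% ± 3.64 (SD, n = 3) of the factor-bound libraries, 2.19 times as much. Start codons held 54.3% ± 2.92 and 61.8% ± 0.714. Coding regions went the other way, from 30.6% ± 2.30 to 15.2% ± 2.96, as did stop codons, from 2.24% ± 0.110 to 0.674% ± 0.154, and 3′ UTRs, from 3.30% ± 0.357 to 1.46% ± 0.463. In each of the 5 areas all 3 factor-bound libraries lay on the same side of all 3 unselected libraries.

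Each factor had a single 40S library, set beside the unselected library of its own strain. The 5′ UTR share was 19% (95% Wilson interval 18.95 to 19.04) with eIF3a, 18.6% (18.52 to 18.59) with eIF3c and 25.1% (25.02 to 25.10) with eIF2β, against 9.09%, 9.57% and 9.89% in the same strains without selection. The coding-region share was 17.7%, 16.1% and 11.9%, in the same order. These intervals cover counting error only. Two-sided exact permutation tests gave p = 0.1 for each area, the smallest value that 3 libraries against 3 allow, so none could pass 0.05. The median over genes of the 5′ UTR share differed by 4.77 percentage points, against 11.4 for summed counts. Strain and factor were confounded, since each factor was tagged in a strain of its own.

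**Figure D1:**
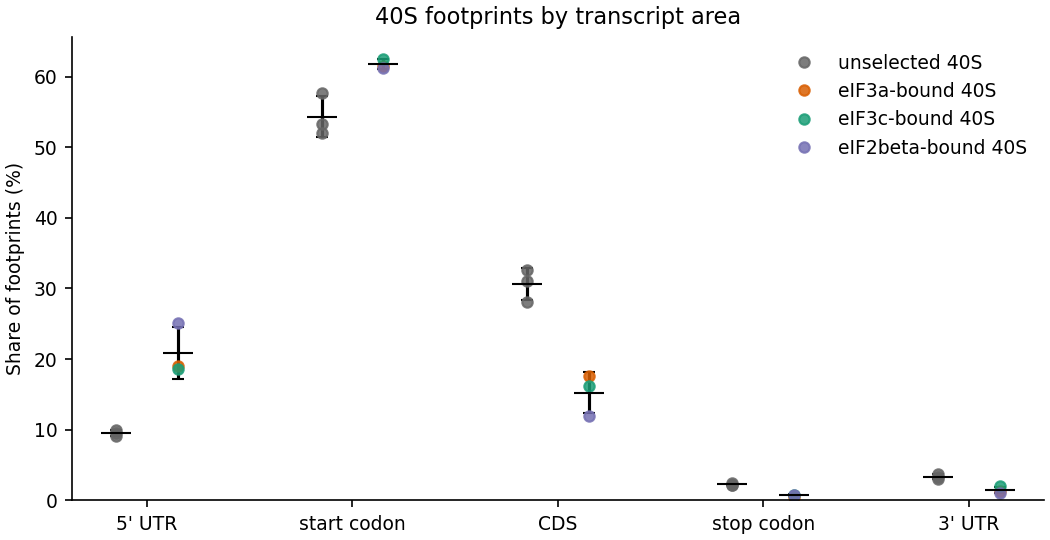
Share of 40S footprints in each transcript area, in percent of a library's counts. Points are the 3 unselected (left of each pair) and 3 factor-bound (right) libraries, with horizontal marks at the mean and bars of 1 SD, and the 5′ UTR share was 9.52% without selection and 20.9% with it, while the coding-region share was 30.6% and 15.2%.

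Gene by gene, few changes of 5′ UTR footprints relative to those of other genes passed the test, which recovered 37% of simulated 2-fold changes, and more passed with the replicate number as a block (105 falls and 32 rises). Of 2036 genes tested, 34 fell and 0 rose at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (217 at an unadjusted p under 0.05), and DESeq2 called 34 falls and 2 rises. Among genes whose libraries did not overlap between the groups, the 10 largest falls were in YIL102C-A (log2 fold −5.42, SE 0.56, edgeR adjusted p = 9.28e-04), YLR154C-G (−5.20), TFC8 (−5.11), ISA2 (−4.82), GET2 (−4.76), DLS1 (−4.53), PIS1 (−4.28), GCV1 (−4.24), UBX2 (−4.21) and BIL1 (−3.67). ISA2 matures iron-sulfur proteins, GET2 is a receptor for tail-anchored membrane proteins, and PIS1 makes phosphatidylinositol. YIL102C-A had 20, 23 and 15 counts without selection and 1, 3 and 1 with it, and TFC8, a subunit of the polymerase III factor TFIIIC, had 8, 8 and 6 against 0, 2 and 0. YLR154C-G (chromosome XII, 462522 to 462671) overlaps the 25S rRNA gene RDN25-2 on the same strand, so its footprints cannot be separated from rRNA fragments.

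GCN4, the transcription factor whose 5′ UTR holds regulatory upstream reading frames, had 9267, 5834 and 8597 leader counts without selection and 22949, 39226 and 52068 with eIF3a, eIF3c and eIF2β. Its relative change was 0.21 on the log2 scale (SE 0.20, edgeR adjusted p = 0.775). The factor genes NIP1, TIF34, HCR1, SUI2, SUI3 and GCD11 did not pass the test either (log2 folds from −0.36 for HCR1 to 0.45 for NIP1), and RPG1, TIF35 and PRT1 had too few leader footprints to test.

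Among 18 gene lists with measured members, 0 passed camera's competitive test on 5′ UTR footprints (lowest adjusted p = 0.252, for small-subunit ribosomal proteins, and adjusted p = 0.952 for every list with an estimated correlation). The only list members to fall were RPS30B (−1.39), 1 of 39 small-subunit ribosomal proteins, and HOM2 (−1.51), 1 of 39 amino acid biosynthesis genes that GCN4 controls. Adjusted over the list alone, the counts were again 1 and 1. With the replicate number as a block, small-subunit ribosomal proteins passed (adjusted p = 0.0358, and 0.952 with an estimated correlation, which was run without the block).

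With the block, rises and falls within lists were 0 and 5 for the ribosomal proteins of either subunit, 2 and 1 for amino acid genes, 0 and 2 for histones, 1 and 1 for the respiratory chain, 1 and 0 for transporters and upstream reading frames, 0 and 1 for biogenesis factors, proteasome subunits and secreted proteins, and 0 and 0 for the rest. Falls numbered 13, 10 and 22 without unselected library 1-1, 1-2 or 1-3, and 17, 11 and 8 without the eIF3a-bound, eIF3c-bound or eIF2β-bound library. Small-subunit ribosomal proteins passed without the eIF3a-bound library (camera adjusted p = 0.00261). The estimated correlation, with 0.952 for this list over all libraries, was not run for the omissions. Among the 10 named genes, those omissions ended 3, 6, 3, 2, 2 and 3 calls. Scaling to all areas together moved the median gene by 1.02 and gave 1168 rises and 27 falls, with 0 falls in every list and from 2 rises of 3 eIF3 subunits to 32 of 44 large-subunit ribosomal proteins.

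At start codons, 52 genes rose and 198 fell among 3868 tested by edgeR (adjusted p under 0.05). Chosen by the same rule, the 10 largest rises were in PKH1 (log2 fold 2.40, SE 0.61, edgeR adjusted p = 0.0482), SSK1 (2.24), YOR1 (2.11), NST1 (2.09), ARP1 (2.04), MTR2 (1.51), CLN3 (1.499), ZDS2 (1.37), DFG5 (1.34) and CWC15 (1.32). Several of these rested on few counts. PKH1 had 3, 0 and 4 counts without selection and 18, 35 and 36 with it. SSK1 had 3, 3 and 1 against 20, 29 and 31. NST1 had 4, 2 and 5 against 26, 48 and 39, and ARP1 had 5, 2 and 3 against 27, 41 and 29. PKH1 is a kinase of sphingolipid signalling, SSK1 an osmosensing response regulator, YOR1 a plasma membrane drug transporter and CLN3 the G1 cyclin, whose mRNA has an upstream reading frame. The largest falls were in YNL042W-B (−4.87, SE 0.39, edgeR adjusted p = 6.92e-04), YOR072W-B (−4.32), FAA3 (−3.36), TMT1 (−2.83), INP1 (−2.64), IMG1 (−2.54), MRPS12 (−2.52), SEC62 (−2.52), ATP11 (−2.49) and FMP52 (−2.48). YNL042W-B (chromosome XIV, 547113 to 547370) and YOR072W-B (chromosome XV, 464469 to 464630) each overlap a tRNA gene on the same strand, YNCN0009W and SUF11. IMG1 and MRPS12 are mitochondrial ribosomal proteins, and SEC62 is a subunit of the endoplasmic reticulum translocon.

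Ribosomal protein lists held more falls than rises at start codons, relative to the median gene. Of 48 large-subunit genes, 16 fell and 2 rose (camera adjusted p = 6.75e-04, and adjusted p = 0.813 with an estimated correlation), with RPL1A at −2.40, RPL8A at −1.52 and RPL38 at −1.48. RPL32 (1.28) and RPL29 (0.68) rose. Of 42 small-subunit genes, 12 fell and 3 rose (adjusted p = 0.0216, and adjusted p = 0.813 with an estimated correlation), led by RPS28A at −1.79, RPS30B at −1.76 and RPS22A at −1.24. Adjusted over the list alone, the falls were 22 and 16 and the rises 3 and 7. The medians of the lists were −0.36 and −0.29, and with library sizes from all areas they were −0.10 and −0.019, with 9 falls and 4 rises of 48 and 9 and 7 of 42. Many of these genes have near-identical copies between which footprints could be split.

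The other 16 lists did not pass at start codons (adjusted p of 0.389 or higher). Other initiation factors had 2 of 14 members up and 0 down, the eIF4A gene TIF2 (0.70) and the eIF4B gene TIF3 (0.73). Proteasome subunits had 4 of 31 up, among them RPN7 (1.02) and RPT1 (0.94), and 1 down. Aminoacyl-tRNA synthetases had 0 of 19 up and 3 down, with ILS1 at −2.14 and GLN4 at −0.94. Rises and falls numbered 1 and 2 of 32 plasma membrane transporters (CAN1 at −1.99, PMA1 at −1.54), 1 and 2 of 29 chaperones (ZUO1 at −1.96), 1 and 2 of 45 amino acid biosynthesis genes (ARO8 at 1.13, ILV6 at −1.33), 1 and 1 of 35 respiratory chain genes (COX9 at 1.14, ATP15 at −0.69), and 1 and 0 of 10 mRNAs with regulatory upstream reading frames (CLN3). There were 0 rises and 2 falls among 29 secreted proteins (UTR2 at −2.15, PHO3), 21 glycolysis genes (PGI1 at −1.02, GPM1) and 10 histones (HHT2 at −0.90, HHT1 at −0.81), and 0 and 1 among 11 elongation factors (TEF2 at −0.82), 62 ribosome biogenesis factors (CBF5) and 19 members of co-translationally assembling complexes (GUS1). Adjusted over the list alone, rises and falls were 6 and 1 for other initiation factors, 4 and 2 for proteasome subunits, 2 and 5 for synthetases, 1 and 2 for transporters, chaperones and amino acid genes, 1 and 1 for respiratory genes and upstream reading frames, 1 and 0 for eIF3, 0 and 3 for glycolysis genes and histones, 0 and 2 for elongation factors and secreted proteins, 0 and 1 for co-translational complexes, and 0 and 0 for biogenesis factors and eIF2 with eIF2B. No eIF3 or eIF2 subunit passed over all genes, although with the block NIP1 (0.45, edgeR adjusted p = 0.00547) and TIF34 (0.60, 9.55e-05) passed upward and TIF35 (−0.40, 0.0128) and HCR1 (−0.54, 0.00164) downward. PRT1 had 0 start codon counts in all 6 libraries.

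With the block, 486 genes rose and 628 fell, and camera called the same pair of ribosomal protein lists alone. Rises and falls within lists were then 3 and 24 for large-subunit and 7 and 19 for small-subunit ribosomal proteins, 14 and 6 for the respiratory chain (camera adjusted p with the block 0.139), 9 and 3 for chaperones (0.641), 10 and 5 for proteasome subunits (0.257), 11 and 9 for amino acid genes, 8 and 12 for biogenesis factors, 8 and 6 for secreted proteins, 6 and 3 for other initiation factors, 2 and 6 for synthetases, 2 and 5 for glycolysis genes, 3 and 5 for transporters, 3 and 3 for co-translational complexes, 1 and 3 for elongation factors, 1 and 4 for histones, 2 and 1 for upstream reading frames, 2 and 2 for eIF3, and 1 and 0 for eIF2 with eIF2B. Without unselected library 1-1, 1-2 or 1-3 the rises were 1, 2 and 14 and the falls 58, 76 and 99, and without the eIF3a-bound, eIF3c-bound or eIF2β-bound library they were 7, 1 and 18 and 66, 45 and 130. Among the 20 named genes, those omissions ended 13, 10, 9, 10, 14 and 10 calls, and small-subunit ribosomal proteins no longer passed without unselected library 1-2 (adjusted p = 0.0919) or the eIF3c-bound library (adjusted p = 0.0882). Scaling to all areas together moved the median gene by 0.26 and gave 290 rises and 130 falls. Within the lists other than ribosomal proteins, rises and falls were then 9 and 0 for the respiratory chain, 8 and 0 for proteasome subunits, 6 and 0 for biogenesis factors and other initiation factors, 5 and 1 for chaperones, 5 and 2 for secreted proteins, 3 and 1 for glycolysis genes, 3 and 2 for amino acid genes, 2 and 1 for synthetases, 2 and 0 for eIF3 and upstream reading frames, 1 and 2 for transporters and histones, 1 and 1 for elongation factors, 1 and 0 for co-translational complexes, and 0 and 0 for eIF2 with eIF2B.

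In coding regions, 690 genes rose and 568 fell among 4797 tested by edgeR, relative to the median gene. By the same rule, the 10 largest rises were in MAN2 (log2 fold 3.13, SE 0.67, edgeR adjusted p = 0.00510), PHO92 (3.07), YML100W-A (3.07), ARR2 (2.98), YGR025W (2.97), SPO75 (2.74), ISF1 (2.73), YKR073C (2.68), PLS1 (2.66) and MIN9 (2.65). Few counts lay behind several of these, also YGR025W (4, 4 and 1 without selection), SPO75 (3, 2 and 7) and ISF1 (8, 3 and 6). MAN2 had 0, 1 and 4 counts without selection and 17, 14 and 13 with it. PHO92 had 5, 1 and 1 against 23, 22 and 12, and YML100W-A had 1, 0 and 4 against 11, 17 and 14. MIN9 (YKL023C-A, chromosome XI, 393146 to 393373) was the most abundant of the 10, with 656, 350 and 477 counts without selection and 2135, 2770 and 3488 with it. It ends within 200 nt of the start of URA6 on the same strand, as YGR025W does before YGR026W and YKR073C before SIS2. The largest falls were in YJL047C-A (−4.36, SE 0.50, edgeR adjusted p = 2.14e-04), IRC13 (−3.85), YOR072W-B (−3.55), YOL013W-A (−3.19), YDR278C (−3.11), YPR108W-A (−3.004), YNL042W-B (−2.98), FAR8 (−2.65), PMA2 (−2.38) and MIP1 (−2.38). YJL047C-A and IRC13 overlap the snoRNA genes SNR60 and SNR17A. MIP1 is the mitochondrial DNA polymerase and PMA2 a plasma membrane proton pump, close in sequence to PMA1. Footprints of MAN2 and DSF1, and of PMA2 and PMA1, could be split between the copies. YOL013W-A, YDR278C and YPR108W-A are not in the reference table used here.

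The direction of change followed coding length. In the shortest tertile of genes (78 to 966 nt) 26.4% rose and 2.31% fell, in the middle tertile 11.8% rose and 8.40% fell, and in the longest (1731 to 14733 nt) 4.77% rose and 24.7% fell. The median log2 fold went from 0.40 to −0.01 to −0.44.

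Several lists moved in coding regions under camera, though each call was lost with an estimated correlation. Coding length was not controlled in these tests, so the list calls cannot be told apart from the length trend above. Of all 4797 genes tested, 690 rose and 568 fell. Elongation and termination factors had 6 of 11 members down and 0 up (adjusted p = 8.77e-04, and adjusted p = 0.445 with an estimated correlation), with YEF3 (elongation factor 3) at −1.61, EFT2 at −1.11 and ANB1 at −0.95. Secreted and cell wall proteins had 11 of 30 down (adjusted p = 6.97e-04, estimated 0.445), among them UTR2 (−1.61), KAR2 (−0.97) and GAS1 (−0.94). Plasma membrane transporters had 10 of 36 down (adjusted p = 6.97e-04, estimated 0.445), with PMA1 at −1.72, SNQ2 at −1.47 and HXT6 at −1.41. Ribosome biogenesis factors had 20 of 64 down and 4 up (adjusted p = 6.97e-04, estimated 0.572), with REA1 at −1.78 and IMP3 at 1.19. Cytosolic chaperones had 11 of 30 down and 2 up (adjusted p = 0.00808, estimated 0.445), with ZUO1 at −1.34, CCT3 at −1.23 and BTT1 at 2.09. Complexes described as assembling co-translationally had 7 of 20 down and 2 up (adjusted p = 0.0142, estimated 0.552), with the fatty acid synthase subunits FAS2 at −1.45 and FAS1 at −1.10. Glycolysis genes had 8 of 21 down and 1 up (adjusted p = 0.0342, estimated 0.572), among them PDC5 (−2.02), PGI1 (−1.06) and TDH2 (0.75). The nuclear-encoded respiratory chain had 10 of 35 up and 3 down (adjusted p = 0.0376, estimated 0.572), with ATP17 at 1.31, COX9 at 1.22 and ATP1 at −0.92. Its rises were relative to the median gene, and with library sizes from all areas 0 of its members rose and 18 fell. Adjusted over the list alone, rises and falls were 0 and 6 for elongation factors, 0 and 11 for secreted proteins and for transporters, 4 and 22 for biogenesis factors, 2 and 12 for chaperones, 2 and 7 for co-translational complexes, 2 and 8 for glycolysis genes, and 11 and 3 for the respiratory chain. With the block they were 0 and 6 for elongation factors, 0 and 15 for secreted proteins, 0 and 18 for transporters, 5 and 24 for biogenesis factors, 2 and 12 for chaperones, 2 and 9 for co-translational complexes, 1 and 9 for glycolysis genes, and 13 and 3 for the respiratory chain. fry, which tests whether the members of a list move one way on balance, passed for elongation factors, secreted proteins, transporters, chaperones, co-translational complexes, the respiratory chain, synthetases, and eIF2 with eIF2B (adjusted p from 0.00558 for synthetases to 0.0463 for co-translational complexes), and not for glycolysis genes (0.0674) or biogenesis factors (0.0683). Gene copies such as EFT1 and EFT2 or TEF1 and TEF2 could share footprints.

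The remaining 10 lists did not pass in coding regions (camera adjusted p from 0.109 for aminoacyl-tRNA synthetases to 0.675 for proteasome and eIF3 subunits). Rises and falls numbered 10 and 1 of 42 small-subunit ribosomal proteins, 13 and 3 of 48 large-subunit ribosomal proteins, 3 and 6 of 20 aminoacyl-tRNA synthetases, 3 and 8 of 46 amino acid biosynthesis genes, 4 and 4 of 14 other initiation factors, 2 and 1 of 6 eIF3 subunits, 0 and 2 of 8 eIF2 and eIF2B subunits, 2 and 4 of 31 proteasome subunits, 2 and 0 of 10 histones, and 0 and 1 of 13 mRNAs with regulatory upstream reading frames. Adjusted over the list alone, they were 10 and 1, 13 and 4, 3 and 9, 3 and 7, 4 and 4, 2 and 2, 0 and 2, 2 and 4, 2 and 0, and 0 and 1, in that order. With the block they were 9 and 2, 14 and 5, 3 and 9, 5 and 15, 4 and 4, 2 and 2, 0 and 3, 3 and 4, 3 and 0, and 0 and 2, again in that order. With library sizes from all areas 0 members of these lists rose, and falls numbered 31, 31, 17, 35, 10, 4, 8, 27, 7 and 9. Among the tagged or partner subunits, NIP1 fell (−1.18, SE 0.19, edgeR adjusted p = 0.00131) and PRT1 (0.49, SE 0.16, edgeR adjusted p = 0.0466) and TIF34 (0.68, SE 0.18, edgeR adjusted p = 0.0168) rose. PRT1 had 0 leader and 0 start codon counts in all 6 libraries. If it initiates downstream of the annotated start, such footprints would count as coding region, so its rise may not be one of coding-region footprints. Scaled to all areas together, PRT1 (−0.59) and TIF34 (−0.41) turned downward without passing. HCR1 missed the threshold (−0.65, edgeR adjusted p = 0.0524) and passed with the block (−0.67, 0.00470), without the eIF3a-bound library (−0.90, 0.0132) or scaled to all areas (−1.69, 1.95e-04). PRT1 lost its call without every library but the eIF3a-bound 40S library (adjusted p 0.0798 to 0.176), under DESeq2 (0.0590) and without the count filter (0.0601). TIF34 lost it without unselected library 1-1 (0.0769) or 1-3 (0.0820).

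Falls numbered 377 without unselected library 1-1 and 350 without 1-3, and all 20 named genes kept their calls without any 1 library. Leaving out a library ended the calls of glycolysis genes (adjusted p = 0.122 without the eIF3c-bound library, 0.0930 without the eIF2β-bound), co-translationally assembling complexes (0.0559 without the eIF3c-bound) and the respiratory chain (0.111 without unselected library 1-1, 0.129 without the eIF3a-bound). Amino acid biosynthesis genes passed downward without unselected library 1-2 (0.00617) or the eIF2β-bound library (0.0362). With an estimated correlation, run on all 6 libraries only, their camera adjusted p was 0.807. Scaling to all areas together moved the median gene by −1.06 and gave 93 rises and 2994 falls.

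**Figure D2:**
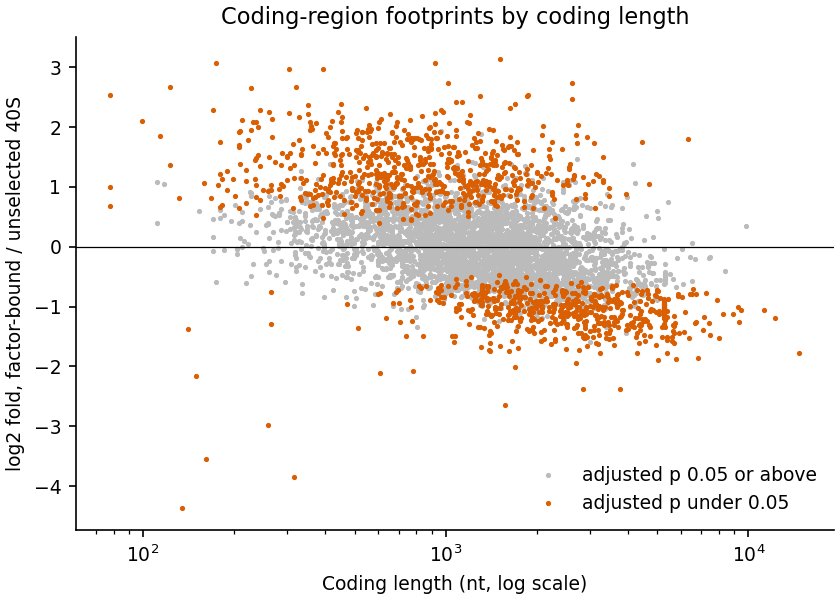
Change of coding-region footprints in factor-bound against unselected 40S (log2 fold relative to the median gene) by coding length in nt on a log scale, 1 point per gene. Of genes in the shortest tertile 26.4% rose, and of those in the longest 24.7% fell (edgeR adjusted p under 0.05).

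The changes with each factor correlated across genes. With each factor-bound library set against the unselected library of its own strain, so that no control was shared, Pearson's r across genes lay between 0.38 and 0.42 for 5′ UTRs, 0.51 and 0.61 for start codons, and 0.62 and 0.69 for coding regions. Spearman's rho was 0.21 to 0.35, 0.50 to 0.60 and 0.61 to 0.68. Genes are not independent replicates, so no p is given.

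Around start codons, 40S and 80S footprints were aligned alike but were distributed differently. The most frequent 5′ end lay 13 nt upstream of the start codon in all 3 unselected 40S and all 3 unselected 80S libraries. Positions −14 to −12 held 42.5% ± 2.04 (SD, n = 3) of the 40S 5′ ends between −80 and +30, against 16.8% ± 1.08 (SD, n = 3) in 80S. A further 35.9% ± 3.21 of 40S ends lay upstream of that peak, against 11.9% ± 1.08, and 6.65% ± 0.603 past the start codon, against 40.5% ± 2.21.

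Footprints of 34 nt or longer made up 15.2% ± 1.6 of the 40S peak and 9.82% ± 2.60 of the 80S peak. Past the start codon, the least used reading frame of each library held 31.6% ± 0.367 of 40S ends and 25.9% ± 1.35 of 80S ends. The most used frame of each library held 36.3% ± 1.17 and 37.6% ± 0.788, with libraries that overlapped. Exact permutation tests gave p = 0.1 for each of these measures (two-sided, n = 3 against 3, the smallest possible; adjusted p = 0.164 over 18 measures) except the most used frame (exact p = 0.2). In a window halved around the peak the difference in peak share was 11.2 percentage points, against 25.7.

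**Figure D3:**
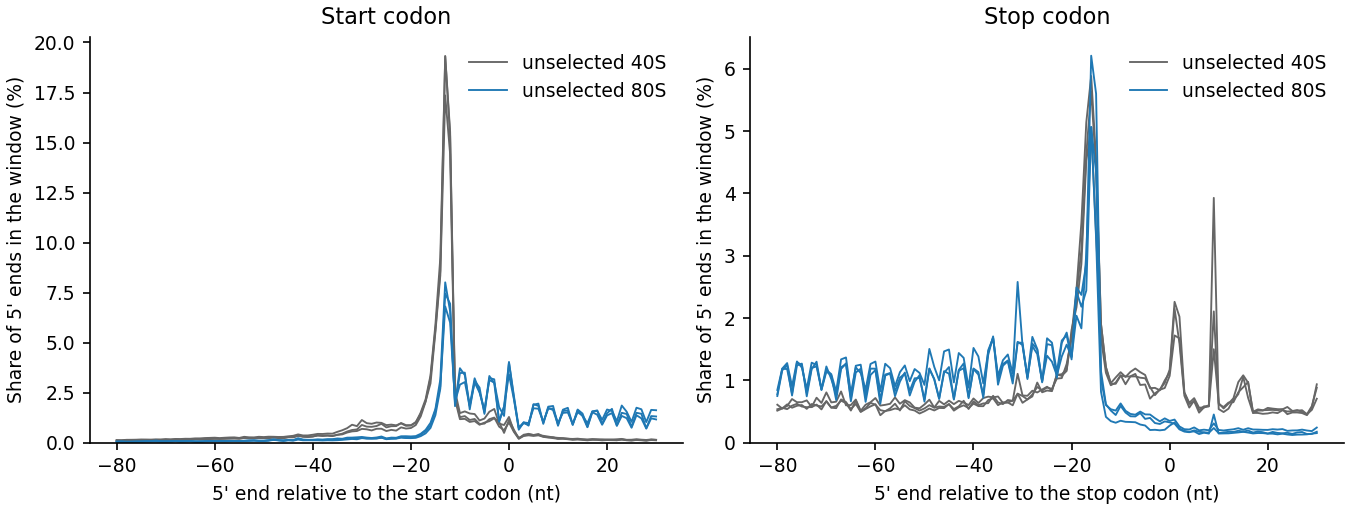
Share of footprint 5′ ends (percent of all in the window) by position relative to the start codon (left) and stop codon (right), in nt, with a line for each library, 3 of unselected 40S and 3 of unselected 80S. The start codon peak at −13 was higher in 40S, and 40S ends past the stop codon made up 22.8% against 5.71% in 80S.

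Factor-bound 40S covered more mRNA on both sides of the start codon. In the authors' means over genes, 3′ ends at +21 to +30 made up 19.6% ± 3.33 (SD, n = 3) of start codon footprints in unselected 40S and 47.3% ± 8.56 (SD, n = 3) in factor-bound 40S, with 49.9% for eIF3a, 54.3% for eIF3c and 37.8% for eIF2β. The most frequent 3′ end was +15 in the 3 unselected libraries and with eIF2β, and +24 with eIF3a and eIF3c. At +15 eIF2β held 8.04% (the authors' limits 7.5 to 8.60) and eIF3a 3.72% (3.46 to 3.96). At +24 eIF2β held 7.44% (6.11 to 9.12), so these limits do not set its +15 and +24 apart. Unselected 40S held 3.54% ± 0.62 at +24. Among 5′ ends, 59.7% ± 5.73 lay upstream of −14 in factor-bound 40S, against 29.7% ± 3.91 without selection, while −13 stayed the most frequent in all 6 libraries. Exact permutation tests gave p = 0.1 for the 5′ ends and for the far 3′ ends (two-sided, n = 3 against 3, the smallest possible). The difference between eIF2β and the eIF3 subunits rests on single libraries and was not tested.

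At stop codons the most frequent 5′ end was −16 in the 3 libraries of 40S and the 3 of 80S. 40S footprints continued past the codon, with 22.8% ± 0.261 (SD, n = 3) of 5′ ends after it, against 5.71% ± 0.840 (SD, n = 3) in 80S. In 40S, positions +1 and +2 together held 2.64 to 3.15 times the share of +4 and +5, and in 80S 1.38 to 1.55 times. Footprints of 23 nt or shorter made up 25.2% ± 4.53 of the 40S peak and 37.3% ± 5.92 of the 80S peak. Exact permutation tests gave p = 0.1 for the share past the codon and for the short class (two-sided, n = 3 against 3, the smallest possible). With class limits 2 nt lower, the difference in the short class was −3.30 percentage points, against −12.1.

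The GCN4 mRNA is the classical case of reinitiation, in which subunits that have translated an upstream reading frame resume scanning. GCN4 lies on chromosome V (138918 to 139763), and positions below are those of the deposited coverage table, whose offset from the start codon was not settled here. Unselected 80S coverage had 4 peaks, at positions 165, 301, 366 and 484, and was highest at 301. Unselected 40S was highest at 181 and factor-bound 40S at 167. The region from 1 to 285 held 28.2% ± 3.59 (SD, n = 3) of the coverage in 80S, 61.7% ± 3.28 in 40S and 75.7% ± 5.70 in factor-bound 40S.

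Over the peak at 165, the share was 7.54% ± 1.70 in 80S, 18.7% ± 1.98 in 40S and 26.1% ± 3.50 in factor-bound 40S. Over the peak at 301, where the order turned, it was 20.3% ± 0.359 in 80S, 15.7% ± 2.23 in 40S and 10.3% ± 3.25 in factor-bound 40S. Over the peak at 366 it was 9.63% ± 1.04, 7.85% ± 2.03 and 3.98% ± 1.07. Over the peak at 484 it was 8.68% ± 2.78, 2.71% ± 0.393 and 1.24% ± 0.388. Past position 499, the share was 22.1% ± 2.68, 5.58% ± 0.967 and 3.08% ± 0.638. Exact permutation tests (two-sided, n = 3 against 3) gave p = 0.1, the smallest possible, in 10 of 12 comparisons. The exceptions were the peak at 301 between factor-bound and unselected 40S (exact p = 0.2) and the peak at 366 between 40S and 80S (exact p = 0.3). The windows were centred on peaks of these same unselected 80S libraries, which favours a higher 80S share in them. The regions overlap in part and are shares of the same total, so the 12 comparisons are not independent.

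**Figure D4:**
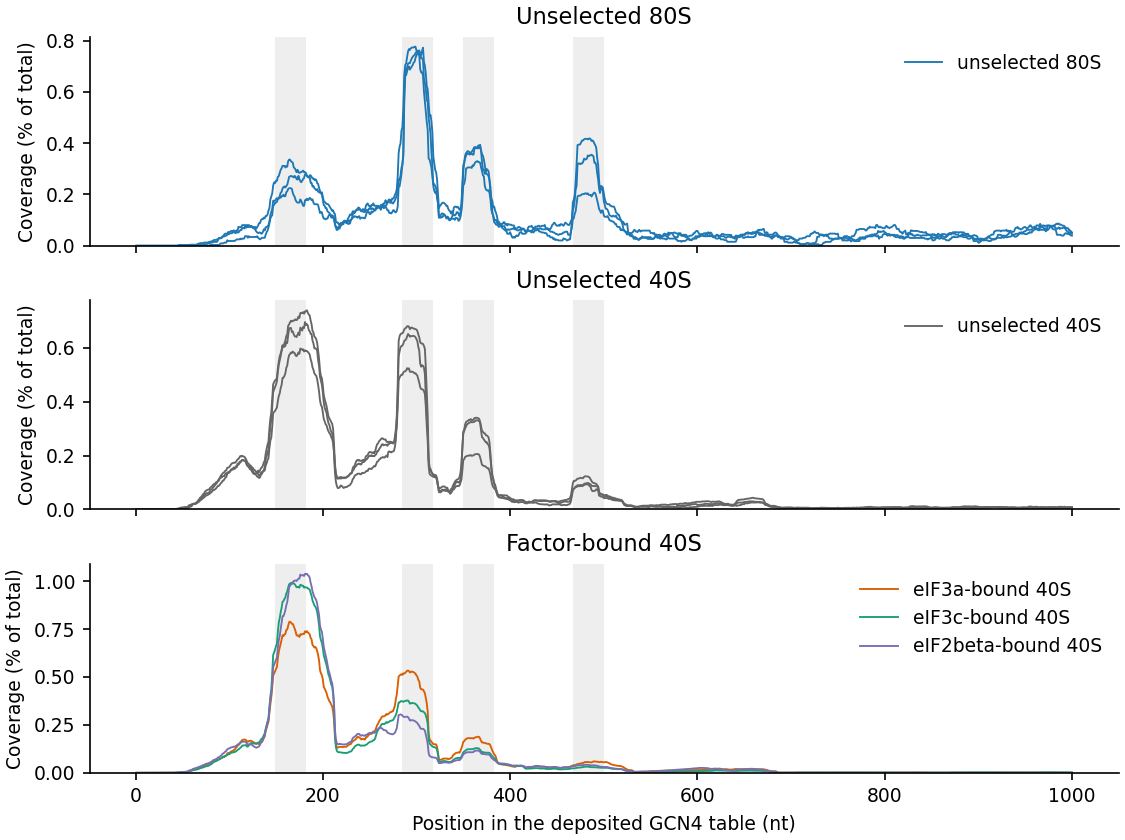
Coverage of the GCN4 mRNA (percent of a library's coverage in the table) by table position in nt, for 3 libraries each of unselected 80S, unselected 40S and factor-bound 40S, with grey bands over the 4 windows around the 80S peaks at 165, 301, 366 and 484. The share before position 286 was 28.2%, 61.7% and 75.7%.

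The 80S ribosomes pulled down with eIF3 subunits ask whether the factor joins nascent partner subunits while these are still being translated. On PRT1 (eIF3b, chromosome XV, 1015361 to 1017652), eIF3a-bound ribosomes were more abundant from about codon 201 to 217 on than before it, relative to unselected 80S. Coverage was not scaled between libraries, so a depletion before that point was not shown. Coverage relative to unselected 80S rose from nt 651, 601 and 601 in the 3 pairs of libraries. Its median over bins was 54-fold, 72-fold and 34-fold higher after that point than before it, and from summed coverage the rise was 18.9-fold, 54.4-fold and 30.2-fold. The share of coverage downstream of the midpoint was 49.4% ± 3.69 (SD, n = 4) in unselected and 66.8% ± 0.915 (SD, n = 3) in eIF3a-bound 80S. Within each library, PRT1 took 92.9% to 93.6% of the coverage summed over the 4 genes in eIF3a-bound 80S, and 26.2% to 29.9% in unselected 80S. TIF35 took 3.18% to 3.68% and 12.8% to 21.4%, in the same order. A higher share of 1 gene lowers those of the others.

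On TIF35 (eIF3g, chromosome IV, 1324477 to 1325301), the share downstream of the midpoint was 42.7% ± 6.50 (SD, n = 4) in unselected and 78.3% ± 5.91 (SD, n = 3) in eIF3a-bound 80S. The rise began at nt 451, 401 and 451 and was 6.18-fold, 7.46-fold and 7.23-fold by medians of bins, or 3.19-fold, 6.54-fold and 6.87-fold from summed coverage. In the eIF3c-bound library coverage of RPG1 (eIF3a, chromosome II, 395383 to 398277) rose 66-fold (51.3-fold from summed coverage) from nt 1501, near codon 501, and 97.2% lay downstream of the midpoint, against 41.8% in the unselected library of that strain. That library also rose on TIF35 from nt 401 (12.6-fold, or 8.80-fold from summed coverage) and on PRT1 from nt 751 (5.87-fold and 5.37-fold), without a replicate. Of its coverage summed over the 4 genes, RPG1 took 52.8%, PRT1 22.1%, TIF35 13.7% and SUI3 11.3%. In the unselected library of that strain the shares were 32.4%, 29.9%, 16.6% and 21.1%. Only the share of RPG1 was higher with eIF3c. That lowers the other shares, so a gain on PRT1 or TIF35 cannot be judged from them.

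In eIF3a-bound 80S, RPG1 itself had 51% ± 5.50 (n = 3) of its coverage downstream of the midpoint, against 42.7% ± 4.07 (n = 4). SUI3 (eIF2β, chromosome XVI, 100496 to 101353) had 38.2% ± 1.51 against 45.2% ± 4.58. By the same rule as for PRT1 and TIF35, eIF3a-bound coverage of RPG1 rose from nt 2801 of 2895 in pair 1-1 (2.01-fold). In pair 2-1 it rose from nt 2601 (2.15-fold), and in pair 3-1 no such point was found. On SUI3 no pair had such a point. The first 75 nt of SUI3 held 20.9% ± 1.22 of its coverage in eIF3a-bound 80S and 7.56% ± 1.62 in unselected 80S, with 4.26% in the eIF3c-bound library. That part held 6.05% ± 3.30 against 2.98% ± 0.560 on RPG1 (0.457% with eIF3c), 9.79% ± 5.56 against 13.4% ± 3.57 on TIF35 (5.42%), and 0.000785% ± 0.000709 against 0.0137% ± 0.0168 on PRT1 (0.0420%).

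Exact permutation tests of the downstream share (two-sided, n = 3 against 4) gave p = 0.0571 for PRT1 and TIF35, the smallest this design allows, and 0.114 for RPG1 and SUI3 (adjusted p = 0.114 for all 4 genes). The first 75 nt gave exact p = 0.0571 for SUI3 (adjusted p = 0.229), 0.229 for RPG1, 0.4 for TIF35 and 0.571 for PRT1. Between matched pairs the log2 ratio of downstream to upstream coverage was 1.05 ± 0.25 (SD, n = 3) for PRT1 and 2.64 between the last and the first of 3 equal parts. For RPG1 it was 0.46 ± 0.50, and 0.18 without pair 2-1.

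**Figure D5:**
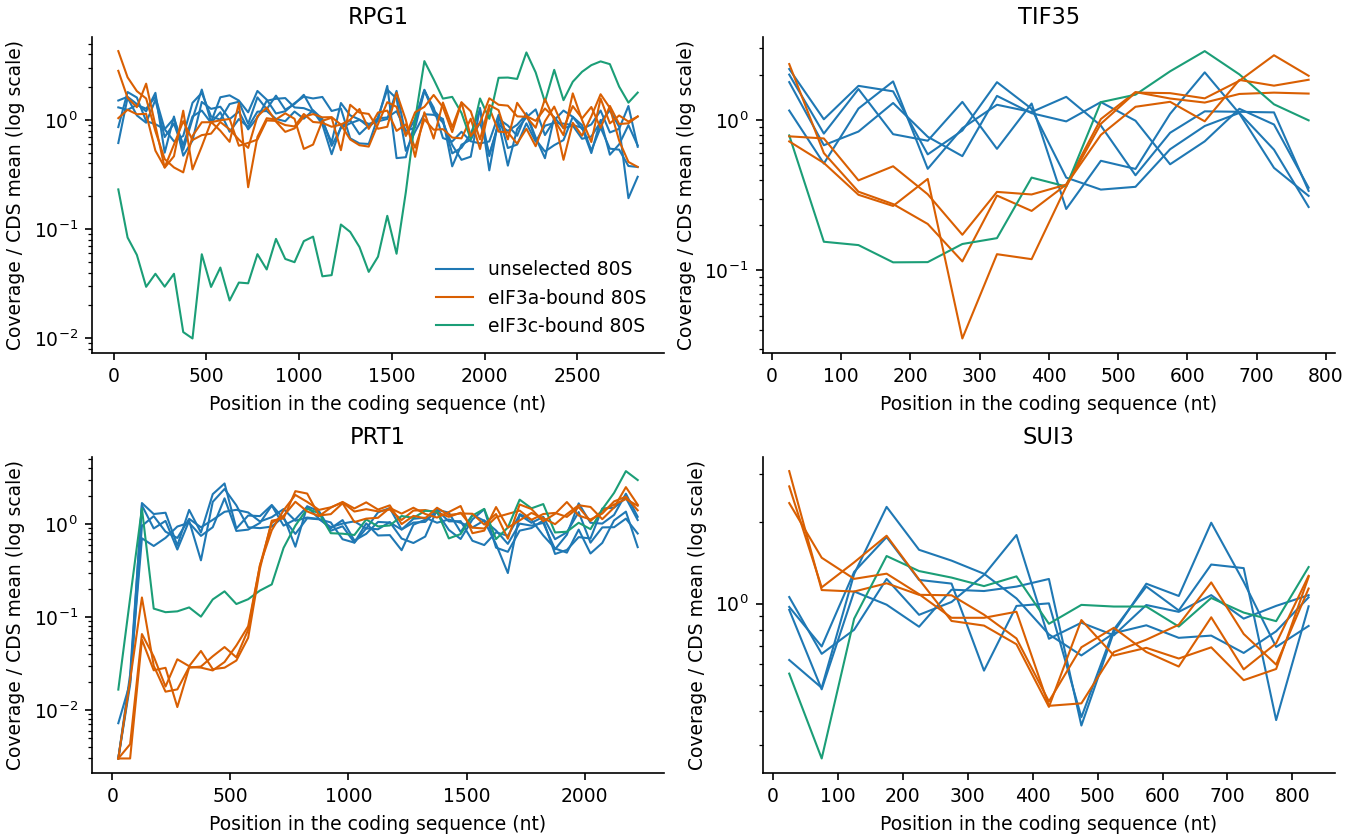
Coverage of RPG1, TIF35, PRT1 and SUI3 by position in the coding sequence (nt, bins of 50 nt), relative to the mean of the coding sequence on a log scale, with values under 0.003 drawn at 0.003 and a line for each library, 4 of unselected, 3 of eIF3a-bound and 1 of eIF3c-bound 80S. On PRT1 the eIF3a-bound lines rose near nt 601, and on RPG1 the eIF3c-bound line rose near nt 1501.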

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

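Every test in this part was chosen after the result it bears on had been seen, except the comparison of start codon with coding-region footprints and the omission of the first 150 nt of SUI3.

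Footprints over stop codons and 3′ UTRs lay outside the main comparisons. At stop codons 71 genes rose and 51 fell in factor-bound against unselected 40S among 497 tested (edgeR adjusted p under 0.05), led by YHR180W (log2 fold 5.67), YGR025W (4.13), YKR073C (3.91), YHR050W-A (3.86) and YOR302W (3.85), the upstream reading frame in the leader of CPA1. The largest falls there were in CIC1 (−3.05), a ribosome biogenesis factor, SOD2 (−2.18), the mitochondrial superoxide dismutase, and GRX3 (−2.09), a glutaredoxin. In 3′ UTRs 29 genes rose and 16 fell among 725, with CWC21 (2.97), YKR073C (2.79) and YMR001C-A (2.56) highest and GEP4 (−4.53), MTC7 (−3.83) and TOF2 (−3.67) lowest. These folds are relative to the median gene, and scaling to all areas together gave 20 rises and 429 falls at stop codons and 12 and 516 in 3′ UTRs. DESeq2 called 52 and 38 at stop codons and 27 and 13 in 3′ UTRs, and the replicate block gave 78 and 58, and 44 and 26. Without unselected library 1-2 the 3′ UTR counts were 10 and 10, and without the eIF3c-bound library 45 and 14.

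Among the stop codon rises, 14 of 70 genes with a known position ended within 200 nt before the next start codon on the same strand, against 7 of 426 other genes (ratio 12.2, Fisher's exact p = 1.93e-08), and their median coding length was 517 nt against 869. Among the 3′ UTR rises it was 11 of 29 against 10 of 696 (ratio 26.4, Fisher's exact p = 1.43e-11), with 390 against 816.5 nt.

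On SUI3, the eIF3c-bound 80S library and the 3 eIF3a-bound libraries moved in opposite directions against the unselected library of their own pair. The log2 ratio of downstream to upstream coverage was 0.24 with eIF3c and −0.46, −0.63 and −0.16 with eIF3a, a difference that was not tested. Both directions turned when the first 150 nt were left out, to −0.24 for eIF3c and 0.07 for eIF3a. No unselected 80S library stood apart from its group in the 12 sets of 4 libraries in which this could be checked. The factor-bound 80S libraries were too few for that check.

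Genes whose coding-region footprints rose with selection had several technical explanations open to a test. Rising genes did not have stronger start codon peaks in the unselected libraries. There the median number of start codon footprints per coding-region footprint was 0.586 in rising and 0.583 in other genes (ratio 1.00). Spill of start codon peaks into the coding area stays open all the same. It was not measured in the factor-bound libraries, and spilled footprints would already count as coding region. Location in the leader of a downstream gene may account for part of the rises: 38 of 689 rising genes ended within 200 nt before a later start on the same strand, against 129 of 4103 others (ratio 1.75, Fisher's exact p = 0.00325), but 651 rising genes had no such neighbour. Short coding regions that catch start codon footprints stay open, since the share of rising genes in the longest tertile, 0.180 of that in the shortest, restates the length trend that prompted the idea and decides nothing. A preference of factor-bound subunits for these mRNAs also stays open and was not tested.

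Of 565 genes of known length whose coding-region footprints fell, 394 lay in the longest tertile of coding length and 37 in the shortest, among these the large falls of YJL047C-A (135 nt) and YOR072W-B (162 nt), with Spearman's rho of −0.486 between coding length and log2 fold across 4792 genes, which are not independent replicates, a trend seen before it was tested. Overlap with non-coding RNA genes was more frequent among them (7 of 565 against 17 of 4227, ratio 3.08, Fisher's exact p = 0.0175), yet 558 falling genes had no such gene within 100 nt, which argues against it for those. Elongating ribosomes left in the unselected 40S fraction could lower the relative coding-region footprints of selected samples on long genes. Past the start codon, unselected 40S kept 23.8% of the depletion of the least used frame of unselected 80S. That lies between the limits of 50% and 10% set for and against the explanation. The fraction also kept 69.3% of the excess of the most used frame. Both frames were picked within each library and not matched between 40S and 80S, so neither value shows that 40S kept the frame of 80S. The answer depends on the measure and the explanation stays open. A true loss of factors from subunits inside coding regions was not tested.

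PRT1 had 0 counts in its 5′ UTR and start codon areas in all 6 libraries of 40S, beside 4382 in its coding region. It shared this with 8 more of the 552 genes that had at least 1000 coding-region counts, among them YDR278C, TRM2 and MAK11. In unselected 80S, PRT1 coverage first reached 10% of its mean at nt 104, 99, 105 and 104 of the annotated coding sequence, and 99 is the lowest of these. A candidate explanation is initiation downstream of the annotated start codon, which the position fits, whereas reads lost at the annotated start for reasons of mapping were not tested. In eIF3a-bound 80S the same point lay at nt 104, 591 and 607, and in eIF3c-bound 80S at nt 83.

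Other splits of the 6 libraries of 40S into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 34 genes by 5′ UTR, 250 by start codon and 1258 by coding-region footprints, and the highest of the others called 0 in each. In each case 1 of 10 splits, the real one, reached its count. Of the 10, the real split and 3 others part all 3 pairs of the same number, and the remaining 6 part 1 pair, with 0 calls in every split but the real one. Each of the others mixes factor-bound and unselected libraries in both groups. Their difference then widens the spread within groups and makes calls unlikely, so these 0 calls do not show what chance alone would give.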

How the results depend on the processing

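The start codon and coding-region gene and list tests, all their alternatives, the counts within lists under other scalings, and the folds from summed coverage were chosen after seeing the data. Apart from the values below, 159 of the main comparisons' alternative values stayed within the limits used, and of the further values for single genes, lists and rises 1057 kept direction and call, 114 lost a call and 21 gained one. Differences held their direction for the 5′ UTR share (11.4 percentage points, 4.77 to 12.5), the start codon peak (25.7, 11.2 to 26.8), long footprints at it (5.41, 4.01 to 6.58), short footprints at stop codons (−12.1, −14.7 to −3.30), the share past stop codons (17.04, 16.8 to 17.5), 3′ ends at +21 to +30 (27.8, 24.3 to 32.5), GCN4 peak 301 (−5.46, −7.17 to −3.94, and −4.57, −5.54 to −3.35), and log2 ratios of RPG1 (0.46, 0.18 to 0.65), TIF35 (2.33, 2.08 to 2.76) and PRT1 (1.05, 0.91 to 2.64). The exact tests behind these are too small to pass 0.05, so their calls show nothing about stability. Of simulated 2-fold changes, 34.8% were recovered at start codons and 47.4% in coding regions, so the gene counts miss many changes of that size.

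The replicate block left the differences at 11.4, 25.7, −12.1, −5.46 and 17.04. With complete pairs these means cannot change, so this shows nothing about stability. An exact sign-flip permutation test gave p = 0.25, the smallest 3 pairs allow. No block for the 80S pairs gave 0.48, 2.31, 1.04 and −0.41 for RPG1, TIF35, PRT1 and SUI3. In the gene tests the block gave 32 rises and 137 calls for 5′ UTRs, 486 rises and 628 falls for start codons, and 1 passing list for 5′ UTRs. It turned the direction of chaperones and transporters in 5′ UTRs (adjusted p 0.985 and 0.985) and of secreted proteins at start codons (0.933). Among lists under camera and the genes named by rule, it changed no call but those given for small-subunit ribosomal proteins, NIP1, TIF34, TIF35 and HCR1. DESeq2 gave 2 rises for 5′ UTRs and 85 at start codons, and no count filter 3 rises and 65 calls for 5′ UTRs. Library sizes from all areas gave 1168 rises and 1195 calls for 5′ UTRs, 290 rises and 130 falls at start codons, and 93 rises and 2994 falls in coding regions, because each area's share of the library then enters the fold. The same scaling turned HCR1 (0.68) and SUI2 (1.02) in 5′ UTRs, SUI3 at start codons (0.12), and PRT1 (−0.59), TIF34 (−0.41), TIF35 (−0.82), SUI2 (−0.75), SUI3 (−1.001) and GCN4 (−0.96) in coding regions, where the last 4 passed downward. SUI2 in 5′ UTRs (−0.01) also turned with DESeq2 size factors (0.020), its Wald test (0.088) and no filter (0.11). With an estimated correlation 0 lists passed at start codons and 0 in coding regions. Between the last and the first of 3 equal parts the eIF3c-bound log2 ratio was 6.12 for RPG1 and 2.63 for PRT1, and without the first 150 nt it was 2.26 for TIF35 and turned to −0.24 for SUI3, as did that of eIF3a for SUI3 (0.072). Except for the all-area scaling, the cause was not tested.

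Leaving out each library in turn gave 8 to 22 calls for 5′ UTRs, 1 to 18 rises and 45 to 130 falls at start codons, 350 to 532 falls in coding regions, and 0 to 1 and 1 to 2 passing lists for 5′ UTRs and start codons. Fewer libraries enter each fit, and the cause was not tested further. Directions of some lists that passed in none of these fits turned in at least 1 omission. Their adjusted p ran in 5′ UTRs from 0.823 to 0.944 for eIF3, 0.654 to 0.947 for eIF2 and eIF2B, 0.505 to 0.947 for elongation and for biogenesis factors, 0.0901 to 0.982 for large-subunit ribosomal proteins, 0.297 to 0.983 for glycolysis, 0.643 to 0.944 for chaperones, 0.544 to 0.947 for synthetases, 0.505 to 0.944 for amino acid genes, 0.4664 to 0.801 for proteasome subunits, 0.823 to 0.983 for secreted proteins and 0.692 to 0.947 for transporters. At start codons it ran from 0.775 to 0.973 for eIF2 and eIF2B, 0.799 to 0.991 for elongation factors, 0.469 to 0.973 for biogenesis factors, 0.837 to 0.973 for glycolysis, co-translational complexes and secreted proteins, 0.318 to 0.948 for amino acid genes and 0.557 to 0.973 for transporters, and in coding regions from 0.255 to 0.919 for proteasome subunits. Log2 folds that crossed 0 ran in 5′ UTRs from −0.011 to 0.85 for NIP1, −0.041 to 0.14 for TIF34, −0.27 to 0.18 for SUI2, −0.045 to 0.67 for SUI3 and −0.033 to 0.45 for GCD11, at start codons from −0.24 to 0.29 for RPG1, −0.42 to 0.19 for SUI3 and −0.23 to 0.79 for GCN4, and in coding regions from −0.28 to 0.73 for SUI3 and −0.26 to 0.23 for GCN4.

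Median, mean and camera's direction differed in sign for biogenesis factors, chaperones, amino acid genes, proteasome subunits, co-translational complexes and transporters in 5′ UTRs, for biogenesis factors, amino acid genes and transporters at start codons, and for eIF3 and proteasome subunits in coding regions. Comparisons of 40S with 80S and of eIF3a-bound with unselected 80S in gene counts, of coverage at the cap and of 80S with mRNA were not run.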

Other observations

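The values in this part were all chosen after the data were seen. At start codons, fry passed for 3 lists that camera did not call. It asks whether the members of a list move one way on balance and does not compare them with other genes. It passed upward for other initiation factors (fry adjusted p = 0.0217) and cytosolic chaperones (0.0441), and downward for aminoacyl-tRNA synthetases (0.0159). fry was run without the block and only with scaling to start codon counts, which sets the reference for its direction. With library sizes from all areas, the synthetase median was 0.034 in place of −0.24, with 2 rises and 1 fall. The medians of chaperones and other initiation factors were then 0.33 and 0.49, in place of 0.059 and 0.22. Under the area scaling chaperones had 1 rise and 2 falls.

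Among the 34 genes whose 5′ UTR footprints fell, 1 had a non-coding RNA gene within 500 nt upstream, against 55 of 2002 other genes (ratio 1.07, Fisher's exact p = 0.616). Their median count over the unselected libraries was 55.5, against 70 for the others.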
